A study of Caenorhabditis elegans with 4 samples.

How the data were processed

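ChIP-seq against MRG-1 and sequencing of input DNA were done on extracts of *fem-2(b245)* adults, with 2 samples of each kind. Per the labels' protocols, ground frozen worms were fixed with 1% formaldehyde for 10 min, the chromatin was sonicated, 5 µg of affinity-purified antibody was used for each precipitation, and libraries were size-selected and amplified by PCR before Illumina sequencing. PCR copies are not independent molecules, and whether they were removed is not given in the sources used here.

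Reads were aligned with BWA to ce10, per the submitters' processing notes, which give no version. Each line of the replicate lists names MACS as the source, and each line of the series list names MACS v2, per the deposited files; the peak cutoff and the control library are not given in the sources used here. WormBase WS220 is named as the genome build of all 3 lists, per the file headers. Each replicate list was deposited for 1 ChIP sample. Whether the series list was called on pooled reads is not given in the sources used here. The score of each peak is the authors' deposited value from the peak caller. Its scale is named in no header. It starts at about 50 in the replicate lists and at 1.32 in the series list, so scores were used only to rank or select peaks within a list, except in 1 added setting that kept peaks with a score of at least 100 in both replicate lists. Peak starts and ends are 1-based. Peaks of a list did not overlap one another.

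Chromosome lengths were not taken from a genome. The highest peak end found in any of the lists was used as the span of each chromosome, which need not equal its full length. Covered bases were the bases inside peaks. Samples were grouped by their titles. Means and SDs are over the 2 ChIP replicates (n = 2). Peaks counted as shared when they overlapped by at least 1 base. Chance overlap came from 1000 rotations of the replicate 2 peaks along each chromosome, one-sided. X and autosomes were compared by the ratio of covered bases, with 95% intervals from 2000 resamples of 200-kb windows. Centres (the central 50% of the span) and arms (the parts on either side) were compared on 5 autosomes with an exact two-sided sign-flip test of the log2 ratio, averaged over the replicates. Shares have 95% Wilson intervals, which cover counting error only and treat peaks as independent, though neighbouring peaks are not. The lists hold no read counts, so no interval or limit based on depth was given.

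The design, the tests, the alternatives and the rule for named items were fixed before the data were examined, except those said to have been added. The rule named the 10 highest-scoring series peaks that meet a peak of both replicates, and members of 11 gene lists. The gene lists (oocyte and early embryo, meiotic prophase, germ granule and small RNA, sperm, chromatin regulators, ribosomal protein, muscle, intestine, neuron, cuticle and hypodermis, chemoreceptor), the position of peaks relative to genes and the GC content of peaks were planned only for an annotation and genome in the build of the files. The gene table at hand is of assembly WBcel235, another build than WS220, and no genome sequence was at hand, so these 3 comparisons were not made and no gene is named at a peak. No values of the input samples were used here.

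Alternatives were a stricter overlap (at least 50% of both peaks, or the midpoint inside the other peak), the better-scoring 50% of each list, peaks per Mb in place of bases, a narrower centre, the series list in place of the replicates, and leaving out each replicate. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated peak lists placed on the same chromosome spans. Lists made with 60% shared peaks gave 60%. The unshared peaks were placed clear of the other list, so chance meetings could not raise this share, as they can in the real lists. It checks the counting only. An X ratio made at 0.2 came out as 0.20, and a centre-to-arm ratio made at 2 came out as 2.01. Of 20 pairs of unrelated lists, 0 passed p = 0.05 in the permutation test by rotation. The unrelated lists had unclustered peaks at random places, as many on X as on each autosome, unlike the real lists. They do not show how the test behaves on unrelated lists that are both denser in the same parts of the chromosomes.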

Results

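Binding of MRG-1 to the genome of adult *Caenorhabditis elegans* was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq). MRG-1 is a chromodomain protein, related to human MRG15, that the germ line needs to develop. The worms carried *fem-2(b245)*, a temperature-sensitive allele of a gene needed for male development, were kept at 20 °C per the series design and were labelled as hermaphrodite young adults with a germ line. The labels' growth protocol speaks of gravid adults instead. An affinity-purified rabbit polyclonal antibody against MRG-1 was used on 2 ChIP samples, and 2 input samples (chromatin DNA taken without the antibody) went with them. The results below rest on 3 peak lists, 1 for each ChIP replicate and 1 for the whole series. No values of the input samples were analysed here, so no background level can be set beside the peaks. The lists give no read counts, so the sequencing depth behind each peak is unknown. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

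MRG-1 peaks were numerous and broad, and covered about an eighth of the nuclear genome, which the lists span up to the last peak of each chromosome. Replicate 1 held 3283 peaks with a median width of 3120 bases, and replicate 2 held 3184 peaks with a median width of 2179 bases. The number of peaks was 3234 ± 70 (SD, n = 2). The covered length differed more, with 15.5 Mb or 15.4% of the spanned bases in replicate 1 and 9.50 Mb or 9.48% in replicate 2, a 1.63-fold difference between the lists. Peaks of at least 5 kb made up 33.3% of the peaks and 66.6% of the covered bases in replicate 1, and 16.2% of the peaks and 39.5% of the covered bases in replicate 2. The widest region was a 34.2-kb peak on chromosome III (WS220, 6362257 to 6396497) in replicate 1 and a 23.1-kb peak on chromosome I (7079101 to 7102194) in replicate 2. The peak caller's scores ran from 50.02 to 3227 in replicate 1 and from 50.01 to 3233 in replicate 2. The widest peaks of replicates 1 and 2 scored 64.33 and 311, below the list medians of 665 and 320. That of replicate 1 was thus among the weaker calls. A score of exactly 3100 was shared by 647 peaks of replicate 1 and 116 of replicate 2, so the strongest peaks were only partly ranked.

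The X chromosome was compared with the 5 autosomes, since MRG-1 has been described as a mainly autosomal protein in germ cells. Peaks were abundant on all autosomes and scarce on X in both libraries. Peaks covered 18.2% of the autosomal bases and 2.44% of X in replicate 1, and 11.5% of the autosomal bases and 0.242% of X in replicate 2. X carried 190 of the 3283 peaks of replicate 1, a share of 5.79% (95% Wilson interval 5.04 to 6.64%), and 27 of the 3184 peaks of replicate 2, a share of 0.848% (0.583 to 1.23%), while it makes up 17.7% of the spanned bases. The intervals cover counting error only. The X peaks were also narrower and lower in score within each list. Their median width was 1981 bases against 3302 on the autosomes in replicate 1, and 1109 against 2187 bases in replicate 2. Their median score was 199 against 759 in replicate 1 and 92.0 against 326 in replicate 2.

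The ratio of coverage on X to coverage on the autosomes was 0.134 in replicate 1 (95% interval from 2000 resamples of 200-kb windows, 0.103 to 0.170) and 0.0211 in replicate 2 (0.00856 to 0.0406). The autosomes were thus covered 7.46-fold more than X in replicate 1 and 47.4-fold more in replicate 2. The geometric mean of both ratios was 0.0532 (0.0312 to 0.0811), so the deficit of X exceeded the variation between windows. The replicates themselves differed in it, as the ratio of replicate 2 was 0.158 times that of replicate 1 (0.0691 to 0.271). X was the lowest of the 6 chromosomes in both replicates; an exact one-sided permutation over chromosomes gave p = 0.167, the smallest value that 6 chromosomes allow. Counted as peaks per Mb instead of bases, the mean ratio was 0.107, and in the better-scoring 50% of each list it was 0.0199. The resampled intervals describe variation along the chromosomes and not between cultures.

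The autosomes differed among themselves as well. Chromosome III was covered to 20.6% ± 5.65 (SD, n = 2) and chromosome I to 20.3% ± 7.10, followed by chromosome II with 15.02% ± 5.00, chromosome IV with 13.1% ± 4.20 and chromosome V with 8.41% ± 2.81. X had 1.34% ± 1.55. The SDs largely carry the higher coverage of replicate 1 on every chromosome. Within each replicate chromosomes I and III were the highest, followed by II, IV, V and X in that order. By number, chromosome I had 50.3 ± 0.188 peaks per Mb, chromosome III 53.0 ± 4.36, chromosome II 36.9 ± 0.0464, chromosome IV 33.3 ± 0.485, chromosome V 23.5 ± 1.22 and X 6.13 ± 6.51. Peak numbers on the autosomes thus varied less between the replicates than covered bases did, and the X number varied most, with 10.7 peaks per Mb in replicate 1 and 1.52 in replicate 2.

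**Figure D1:**
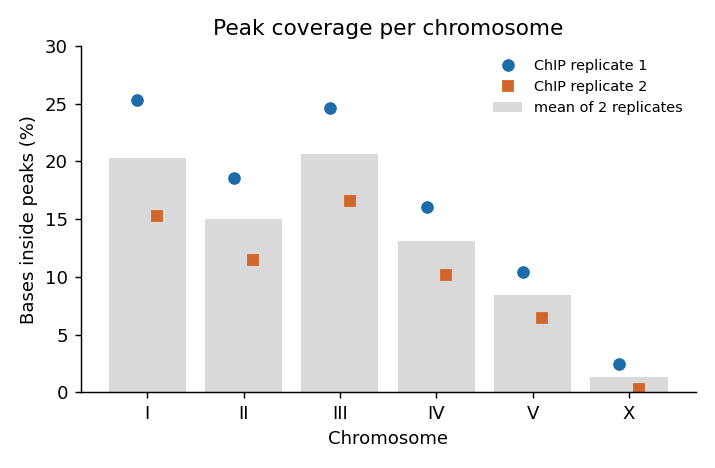
Percent of bases inside MRG-1 peaks (y axis) for each chromosome (x axis), with ChIP replicate 1 as circles, ChIP replicate 2 as squares and their mean as bars. X was the lowest chromosome in both replicates, at 2.44% and 0.242%, and chromosome V was the lowest autosome, at 10.4% and 6.42%.

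The central 50% of each chromosome was compared with its arms on either side, because genes expressed in the *C. elegans* germ line tend to lie in the centres of autosomes. MRG-1 peaks covered more of the centre than of the arms of all 5 autosomes, in each replicate. On chromosome III the centre was covered to 27.02% ± 5.32 and the arms to 14.2% ± 5.98 (SD, n = 2). Chromosome I had 26.4% ± 8.03 in the centre and 14.1% ± 6.17 in the arms, chromosome II 19.5% ± 5.32 and 10.6% ± 4.67, and chromosome IV 16.9% ± 4.79 and 9.29% ± 3.599. Chromosome V had the highest centre-to-arm ratio, 2.45 ± 0.413, with 11.8% ± 3.40 in the centre and 5.01% ± 2.23 in the arms. X went the other way, with a ratio of 0.751 in replicate 1 and 0.306 in replicate 2. Without the first 200 kb on its left the ratios were 0.862 and 0.652. The replicate 2 ratio rests on only 27 X peaks, 7 of them in that stretch, with 0.114% of the centre and 0.370% of the arms covered. Over the 5 autosomes the geometric mean ratio was 2.01, with 1.78 in replicate 1 and 2.26 in replicate 2. Counted as peaks per Mb instead of bases, it was 1.37. The exact two-sided sign-flip permutation test over 5 autosomes gave p = 0.0625, the smallest value this number of chromosomes allows, so the threshold of 0.05 could not be reached.

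The arms of one chromosome were not alike. In replicate 1 the right arm of chromosome III was covered to 23.3% and the left to 13.5%, and the right arm of chromosome II to 17.8% and the left to 9.93%. In replicate 2 these values were 12.5% and 7.40% on chromosome III, and 10.3% and 4.25% on chromosome II. Chromosome IV had more coverage in its left arm, 13.7% against 9.93% in replicate 1 and 7.47% against 6.03% in replicate 2. The right arm of chromosome IV also held the longest stretch without a peak in replicate 1, 753 kb (15648467 to 16401703), most of which was also free of peaks in replicate 2, where the longest stretch on that chromosome ran over 467 kb (15944236 to 16411438). On chromosome V the longest peak-free stretch lay in the left arm in both replicates, over 682 kb (2877123 to 3558686) in replicate 1 and 881 kb (2698009 to 3578691) in replicate 2. The series list had peaks there, at 0.669% of the window from 3200001 to 3400000. Its own longest peak-free stretch on chromosome V lay in the right arm, over 369 kb (19200123 to 19568986). The longest peak-free stretch of replicate 2 in the genome was 2146 kb on X (7770043 to 9916209). Replicate 1 and the series list had peaks in every full 200-kb window of that stretch.

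**Figure D2:**
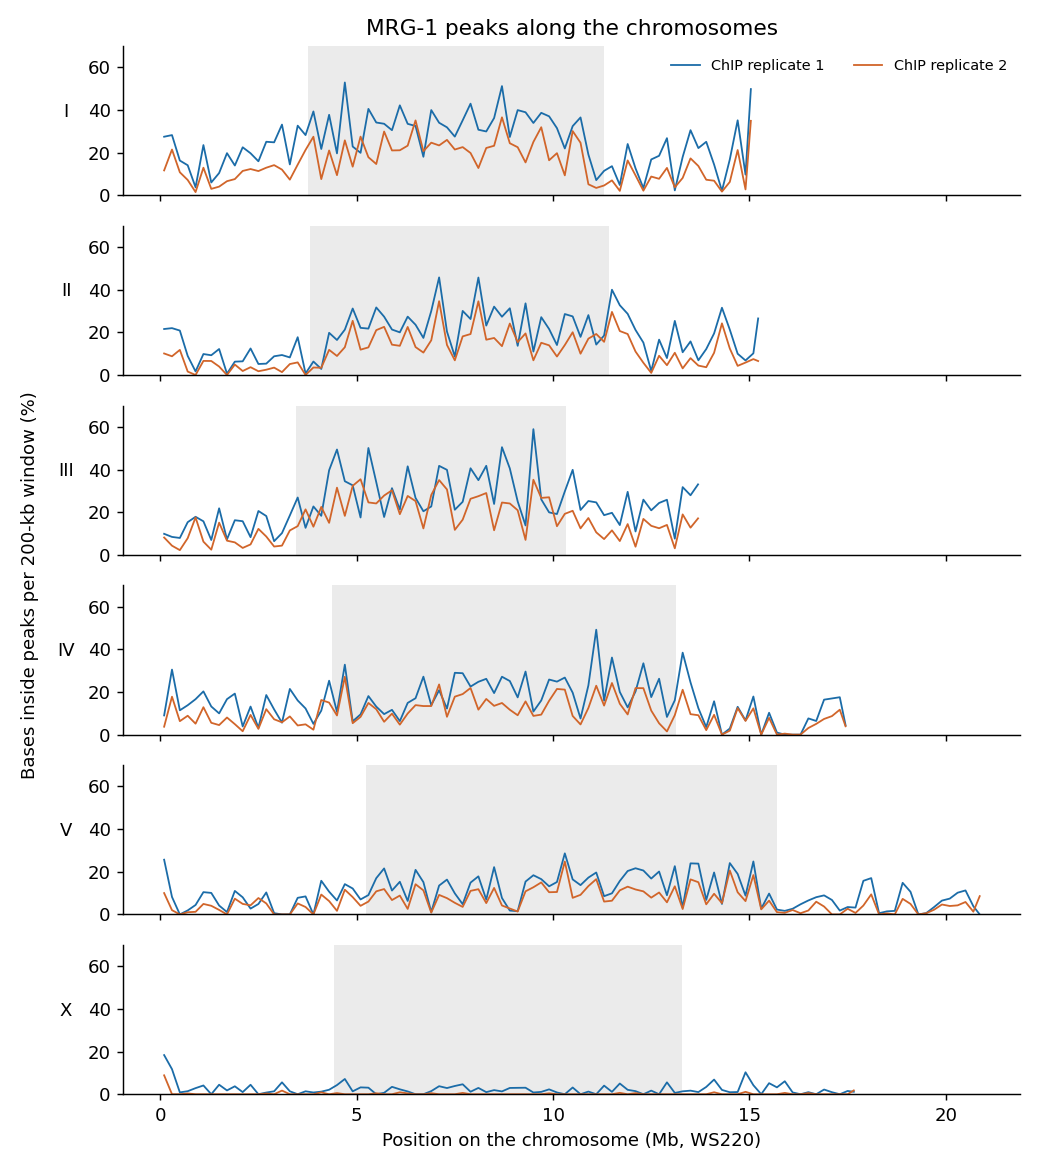
Percent of bases inside MRG-1 peaks in successive 200-kb windows (y axis) along the 6 chromosomes (x axis, position in Mb, WS220), for ChIP replicates 1 and 2; the shaded band is the central 50% of each chromosome, and the last window of each is shorter. Both replicates rose in the autosome centres and stayed low on X, where the first 200 kb on the left was the most covered window, at 18.4% in replicate 1 and 8.87% in replicate 2.

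The replicate lists were compared with each other to see whether the 2 libraries marked the same places. Most peaks of replicate 2 touched peaks of replicate 1, and the strong peaks of replicate 1 were nearly all touched in turn. The match in extent was looser, as 36.97% of the replicate 2 peaks and 35.9% of the replicate 1 peaks passed when 50% of both peaks had to overlap. Of the 3184 peaks of replicate 2, 2865 met a replicate 1 peak by at least 1 base, which is 90.0% (95% Wilson interval 88.9 to 91.0%). Of the 3283 peaks of replicate 1, 1959 met a replicate 2 peak, which is 59.7% (58.0 to 61.3%). The shared bases made up 51.7% of the bases covered in either list (Jaccard index). When the peaks of replicate 2 were rotated along each chromosome 1000 times, the means were 28.2%, 23.2% and 8.22%, and the highest rotations gave 38.6%, 30.2% and 13.2%. Each one-sided permutation test by rotation gave p = 0.001, the smallest value that 1000 rotations can give.

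The share of replicate 1 peaks found in replicate 2 rose with the score, from 12.9% (10.8 to 15.4%) in the lowest of 4 score groups to 37.4% (34.1 to 40.8%), 89.1% (86.8 to 91.1%) and 99.3% (98.4 to 99.7%) in the highest. In replicate 2 the share ran from 81.9% (79.1 to 84.4%) in the lowest group to 93.7% (91.8 to 95.2%) in the highest. No chance share is given for single score groups, and peak width was not held constant across them. The lowest group of replicate 1 lay below the rotation mean of 23.2% for all its peaks, so its meetings need not be reproduced peaks. On the autosomes 62.7% (60.9 to 64.3%) of the replicate 1 peaks were met, with chromosome I at 59.0% and chromosome V at 65.3% as the extremes. On X only 21 of the 190 peaks of replicate 1 were met, which is 11.1% (7.34 to 16.3%), whereas 24 of the 27 X peaks of replicate 2 met a replicate 1 peak. Across 415 autosomal windows of 200 kb, coverage in the replicates had a Pearson r of 0.870 and a Spearman rho of 0.902; neighbouring windows are not independent replicates. Across the 89 windows of X, r was 0.655 and rho 0.262, and 70 of these windows held no base of a replicate 2 peak. The first window on the left weighs heavily on r. It had 18.4% in replicate 1 and 8.87% in replicate 2, where the next highest X window had 1.81%.

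**Figure D3:**
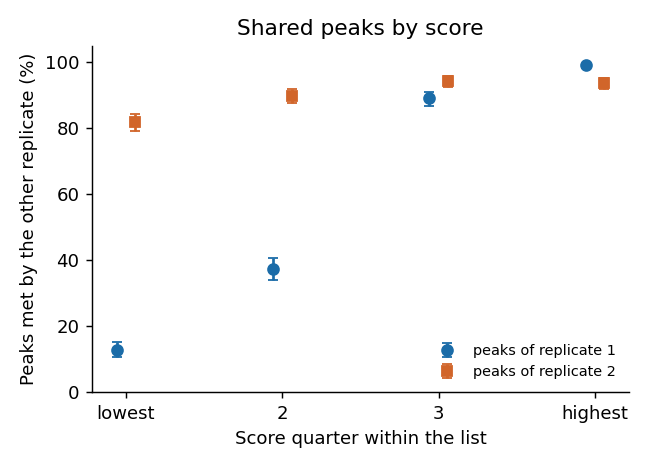
Percent of the peaks of each replicate that met a peak of the other (y axis), by score group within the list, 4 groups of equal size (x axis, lowest to highest); bars are 95% Wilson intervals. The replicate 1 share rose from 12.9% to 99.3%, and the replicate 2 share was above 80% in every group, from 81.9%.

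The list deposited for the whole series, which names MACS v2 where the replicate lists name MACS without a version, was set against the replicate lists to see what it holds. It had 12447 peaks, 3.79-fold more than replicate 1, with a median width of 449 bases, and 12440 of them lay on the 6 nuclear chromosomes, covering 13.8 Mb or 13.7% of the spanned bases. It touched 99.9% of the replicate 1 peaks and 98.2% of the replicate 2 peaks by at least 1 base, and 42.9% and 66.9% when 50% of both peaks had to overlap. Of its nuclear peaks 31.5% (30.7 to 32.3%) met peaks of both replicates, 42.9% (41.99 to 43.7%) met replicate 1 only, 3.19% (2.90 to 3.51%) met replicate 2 only and 22.4% (21.7 to 23.2%) met neither. The peaks over both replicates had a median width of 1542 bases and held 66.1% of the bases of the list, and those over neither had a median width of 244 bases and held 6.68%. Replicate 1 peaks held a median of 2 series peaks each and up to 23, and replicate 2 peaks a median of 1 and up to 9. X had 498 series peaks covering 1.48% of its bases, against 16.4% on the autosomes, a ratio of 0.0901 (95% window interval 0.0688 to 0.116). With at least 50% of both peaks required to overlap, the share over neither replicate was 79.2%, and the order of the single replicates turned, to 3.66% for replicate 1 only and 9.47% for replicate 2 only.

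The 10 highest-scoring series peaks that met both replicates lay on autosomes, 5 of them on chromosome IV and none on X. X held only 39 of all 3922 series peaks that met both replicates, or 0.994%, so its absence among 10 adds little. The first was on chromosome II (WS220, 2751287 to 2752777), the next on chromosome III (11007749 to 11010441) and chromosome IV (16862518 to 16867015). They were followed by peaks on chromosome I (8726731 to 8731596), chromosome IV (14464193 to 14468910 and 5158840 to 5161775) and chromosome V (19643088 to 19645799). The last of them were on chromosome IV (2676427 to 2677847), chromosome II (12459535 to 12461321) and chromosome IV (13091666 to 13101652). Their series scores ran from 103.67 to 129, and their widths from 1421 to 9987 bases. The replicate 1 peaks at these places had the score 3100 in 7 cases and those of replicate 2 in 2 cases. The lowest-ranked replicate peak at any of these places stood at the 71st percentile of scores in replicate 1 and at the 53rd in replicate 2. The peaks are given by position only, as genes were not assigned to them here.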

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

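No test was made in this part, and the mitochondrial peaks were looked at only after they were seen in the series list. It held 7 peaks on mitochondrial DNA, a sequence that no comparison above used, while both replicate lists held 0 peaks there. They lay between bases 169 and 12804, with a median width of 232 bases and a highest score of 7.28, and 49.9% of the nuclear series peaks scored as high. No explanation was tested for them. With 2 samples in a group, no sample was tested as an outlier.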

How the results depend on the processing

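The settings that kept peaks scoring at least 100, moved replicate 2 peaks by 20 to 200 kb, set X beside the autosomes or left out the left 200 kb of X were chosen after seeing the data; the others were planned. The overlap of the replicates stayed above chance in all 10 alternatives run, at a permutation p of 0.001 each, 7 by rotation and 3 by the shorter moves, with 35.9% and 36.97% of the replicate 1 and replicate 2 peaks shared when 50% of both peaks was required, against 4.57% and 4.71% by rotation. With shifts of 20 to 200 kb the chance values were 24.4% and 30.7%, close to those of full rotation. The X ratio stayed below 1, with its window interval, in all 9 alternatives, but its size did not hold: it was 0.0211 without replicate 1, 0.134 without replicate 2, 0.0901 in the series list, 0.107 as peaks per Mb, 0.0199 in the better-scoring 50%, 0.0430 at scores of at least 100 and 0.0394 without the left 200 kb of X (0.0125 without replicate 1 as well, the lowest value of all). Autosome centres stayed above the arms in all 9 alternatives, from 1.37 as peaks per Mb to 2.26 without replicate 1 (1.78 without replicate 2); with X added to the autosomes the ratio was 1.58 and the exact permutation p 0.188, or 1.70 and 0.0625 without the left 200 kb of X. The series list depended most on the rule for overlap. Requiring 50% of both peaks gave 7.65% of series peaks over both replicates, 3.66% over replicate 1 only, 9.47% over replicate 2 only and 79.2% over neither, and 42.9% and 66.9% of the replicate 1 and 2 peaks were then in the series list, since narrow series peaks cannot fill 50% of a broad replicate peak. The better-scoring 50% of each list held 1642, 1592 and 6227 peaks in replicate 1, replicate 2 and the series, by construction, and gave 31.1% over replicate 1 only, 5.38% over replicate 2 only and 32.8% over neither, with 100% and 99.9% of the replicate 1 and 2 peaks in the series list. No paired analysis was possible because no values of the input samples were analysed here. The alternatives planned for gene positions, gene lists and GC content were not run, for want of an annotation and sequence in the files' build. Read depth is unknown, which limits any reading of a missing peak: it is a place where the caller made no call.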

Other observations

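The tests of isolated peaks and of rotated X peaks at the left end were chosen after the results they bear on were seen. So were those of series peaks inside replicate peaks and of the pairing centre arms. The others below also addressed patterns already seen in the lists, and only their predictions were set before the test values. The left end of X stood apart from the rest of that chromosome. Its first 200 kb, 1.13% of X, held 11 of the 190 X peaks of replicate 1, 7 of the 27 of replicate 2 and 40 of the 498 of the series list. It was the most covered of the 89 windows of X in each list, with 18.4%, 8.87% and 13.9% of its bases inside peaks. The remainder of X was covered to 2.26%, 0.143% and 1.33%. In replicate 2 this one window held 41.4% of all X bases inside peaks, and without it the autosome-to-X difference in coverage of replicate 2 grew from 47.4-fold to 79.9-fold. The next most covered X windows were 200001 to 400000 in replicate 1 and the series list, and in replicate 2 the short last window from 17600001, at 1.81%.

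2 explanations for the left end were tested. A general effect of chromosome ends on mapping or calling was tested on the other 11 ends: their median ratio of end to remainder was 0.571 in replicate 1 and 0.826 in replicate 2, which argues against it, although the left end of chromosome V also stood high at 2.503 and 1.57, and the right end of X at 4.36 in replicate 2 (0.264 in replicate 1). Chance placing of clustered X peaks was tested by 1000 rotations. As many covered bases fell there in 6 of them in replicate 1 and 2 in replicate 2 (one-sided permutation p of 0.007, or 0.699%, and 0.003). These values are too favourable because the window was picked from the same lists. It was the most covered of 89, so few rotations could match it in any case, and the test cannot decide on chance placing. The left tip of X is known as a region where the germline histone methyltransferase MES-4 is found, unlike the bulk of X. A link between MES-4 and MRG-1 there is only a hypothesis and was not tested. MRG-1 ChIP in worms without MES-4 would bear on it, but would not decide it if such worms had fewer germ cells. Repeated sequence in this stretch was not tested and stays open.

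The X chromosome had 190 peaks in replicate 1 and 27 in replicate 2, against 3093 and 3157 on the autosomes, although both belong to one group. A replicate 2 list that reached fewer weak peaks on all chromosomes alike would lose autosomal peaks of the same score and width as often. It met 40.3% of such matched autosomal peaks (95% range of 10000 draws 34.7 to 46.3%) but 11.1% of the X peaks. This argues against that account as the whole of it, unless chance meetings raised the autosomal share. Chance meetings in the denser autosomes were examined on replicate 1 peaks with no other replicate 1 peak within 10 kb. Of these, 12 of 116 X peaks, 10.3%, were met, against 38.1% (31.03 to 45.7%) of matched autosomal peaks. This cannot decide on chance meetings, since the choice does not thin the replicate 2 peaks on which they depend. Rotation gave a mean of 23.2% for replicate 1 peaks of all chromosomes together. Whether the X peaks missing from replicate 2 were stray calls of replicate 1 cannot be told apart with the series list, since 98.8% of them met a series peak but so did 99.9% of all replicate 1 peaks. A difference in the control library or in the share of body cells to germ cells was not tested, and no biological explanation was tested because the design gives the replicates no difference.

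The series list had 3.79-fold more peaks than replicate 1, and splitting of broad replicate peaks into narrower pieces was tested as the source. The share of series peaks over a peak of either replicate was 77.6%. It lay between the 80% needed for splitting as the whole source and the lower limit set against it, so this rule decided neither way. The 2790 series peaks over neither replicate, with a median score of 4.40 against 21.2 for those over both, are not pieces of any replicate peak. They argue against splitting alone. For the 9650 that lie over a replicate peak, splitting cannot be told apart from separate calls, as 68.6% of replicate 1 peaks but 40.8% of replicate 2 peaks held 2 or more series peaks.

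A further hypothesis was that MRG-1 peaks are sparser on the autosome arm that holds the meiotic pairing centre, the end at which homologous chromosomes pair. These arms were taken from general knowledge (right on I and V, left on II, III, IV and X), and a mistaken entry for IV and V was put right after the values had been seen. The opposite arm was the more covered in both replicates on 4 of 5 autosomes, by 1.80-fold and 2.42-fold on chromosome II, 1.73-fold and 1.69-fold on chromosome III, 1.22-fold and 1.43-fold on chromosome V, and 1.15-fold and 1.16-fold on chromosome I. Chromosome IV went the other way, at 0.722 and 0.808. X had 0.777 and 0.348 with its first 200 kb on the left, but 1.01 and 1.23 without it. Its direction in the replicates thus rested on that stretch. In the series list the X ratio was 0.683 with the stretch and 0.917 without it, so the direction did not turn there. The geometric mean ratio was 1.33 and the exact two-sided sign-flip permutation p was 0.188, with 0.0625 as the smallest that 5 autosomes allow, so the pattern cannot be told apart from chance with so few chromosomes.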
